A study of Mus musculus with 11 samples.

How the data were processed

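RNA sequencing of sorted microglia was analysed in 11 mouse libraries of 4 genotypes. Per the labels' protocols, RNA was extracted from cells isolated by flow cytometry and libraries were made with the SMART-Seq v4 kit, a full-length cDNA method that does not mark strand. Per the submitters' processing notes, STAR 2.7.3a and featureCounts 1.6.4 were used with the builds GRCm38.p6 and mm10. The authors deposited a table of whole-number read counts per gene, with 55401 rows and 1 column per library, and the deposited counts carry no normalisation. The annotation release, the treatment of reads with several positions and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and members of multigene families such as the paired receptors of the Lilr, Pir and Siglec families are uncertain. All 37 rows of chromosome M held 0 counts in every library, so mitochondrial transcripts could not be measured.

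Groups were taken from the genotype label. Replicate numbers within a group follow the order of the samples and pair nothing. Library totals ran from 29490567 to 66637052 counts, and a floor of 3 counts in a library corresponded to 0.0477 to 0.1 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries held identical values. The labels used here do not say how the libraries of a group relate to animals or litters, so p values measure the spread between these libraries.

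Genes were kept with filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 20390. Library sizes were scaled by TMM, and CPM values given here use the scaled sizes. A single model with 1 coefficient per group was fitted over the 11 libraries with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), so that all groups share the estimate of spread. Adjusted p values are Benjamini-Hochberg values from this edgeR test within each comparison, with a threshold of 0.05, and the standard error (SE) of a log2 fold change was taken from the test statistic. The contrasts were those between pairs of genotypes described below and the interaction of Tyrobp and Inpp5d.

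The design, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The rule named Tyrobp, Inpp5d, Trem2 and App always. It named up to 8 higher and 8 lower genes with the largest fold changes among called genes that had a mean of at least 5 CPM in a compared group and no overlap between the libraries of both groups, leaving out genes without a named symbol. Where fewer than 3 genes qualified, the 5 genes per direction with the smallest p were taken and are given as not passing. From each list up to 4 members with the smallest p were named, as were genes called with opposite signs in the Tyrobp-/- comparison and in the compound mutant against Tyrobp-/-. Lists were tested with camera (limma 3.58.1) on voom log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. The mitochondrial list had no tested member, which left 31 lists.

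The procedure was tested on simulated data with 200 changed genes among 20390. The changed genes were drawn from the 10460 with a mean of at least 5 CPM, so the shares called do not cover genes of lower expression. For Tyrobp-/-;NLGF against NLGF, 14.9% of simulated changes of 2-fold and 72.7% of those of 4-fold were called. These shares were 49.3% and 84.8% for Inpp5d+/-;NLGF against NLGF and 20.9% and 75.8% for the compound mutant against Tyrobp-/-;NLGF. For the compound mutant they were 32.8% and 75.8% against NLGF, and 32.8% and 74.2% against Inpp5d+/-;NLGF.

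The alternatives were RLE and upper-quartile scaling, no filter, a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, fits on 2 groups only, a fold threshold of 1.5, an additive model, exclusion of chromosomes X and Y and of 10 Mb around both targeted genes, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, and each library left out. A sex covariate was not run, because all 11 libraries fell in 1 class by Xist and Y-linked counts. After the data were seen, a covariate for neutrophil markers and a fit without the 2 libraries with most S100a8 were added. Gene coordinates are those of the deposited table. The result of 1 named gene is not reported here.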

Results

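The study asked how Inpp5d, which encodes the phosphatase SHIP1, bears on the loss of signalling through the receptor TREM2 in a mouse model of amyloid deposition. Tyrobp encodes DAP12, the adaptor through which TREM2 signals. All mice carried the App knock-in alleles of the NLGF line, which gives amyloid plaques, on a C57BL/6 background, and were 9 to 10 months old. Live CD11b+/CD45+ cells were sorted from brain as microglia and sequenced in 3 NLGF, 3 Inpp5d+/-;NLGF, 2 Tyrobp-/-;NLGF and 3 Tyrobp-/-;Inpp5d+/-;NLGF libraries, the last called the compound mutant here. Total counts ran from 29490567 to 66637052 per library, and 20203 to 22662 genes were detected. The numbers in the sample titles of the Tyrobp-/- libraries and of the others fall in separate ranges. Handling or litter therefore cannot be told apart from the Tyrobp genotype in any comparison between Tyrobp genotypes below. On multidimensional scaling, the first dimension (21.2% of the variance) placed the 5 Tyrobp-/- libraries on the positive side and the 6 other libraries on the negative side. Among the 5 Tyrobp-/- libraries the order on this dimension was also that of their neutrophil marker means. Tyrobp-/-;NLGF replicate 1 was highest (3.29) and compound replicate 1 lowest (0.482). Their neutrophil list means (log2 difference from NLGF) were 8.358 and 2.015. The first dimension therefore cannot be read as the Tyrobp genotype alone. Compound replicate 1 stood apart on the second dimension, at -3.85, where every other library lay between -0.237 and 1.08. It also held the most RNA of neuron and astrocyte markers, with list means (log2 difference from NLGF) of 3.593 and 1.814, against -1.012 to 0.757 and -0.805 to 0.985 in the other libraries.

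The targeted genes were examined first. Tyrobp (ENSMUSG00000030579.10, chromosome 7, 30413760 to 30417585, GRCm38) was at 2190 ± 318 CPM in NLGF (SD, n = 3) and 2150 ± 179 in Inpp5d+/-;NLGF (n = 3). It was at 7.98 ± 1.36 in Tyrobp-/-;NLGF (n = 2) and 5.16 ± 2.81 in the compound mutant (n = 3). Inpp5d (ENSMUSG00000026288.14, chromosome 1, 87620312 to 87720507) was at 318 ± 116 CPM in NLGF and 230 ± 45.5 in Inpp5d+/-;NLGF, a difference within the spread (log2 fold change -0.47, SE 0.25, adjusted p = 0.952). Within the Tyrobp-/- background it was at 448 ± 1.26 without and 236 ± 40.3 with the Inpp5d+/- genotype, with no overlap of libraries (log2 fold change -0.92, SE 0.28), although the adjusted p was 1 over all genes. Trem2 and App passed the threshold in no comparison. Trem2 was at 2400 ± 355 CPM in NLGF and 2030 ± 25.6 in Tyrobp-/-;NLGF, and App was at 83.6 ± 10.6 and 98.2 ± 2.69.

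**Figure D1:**
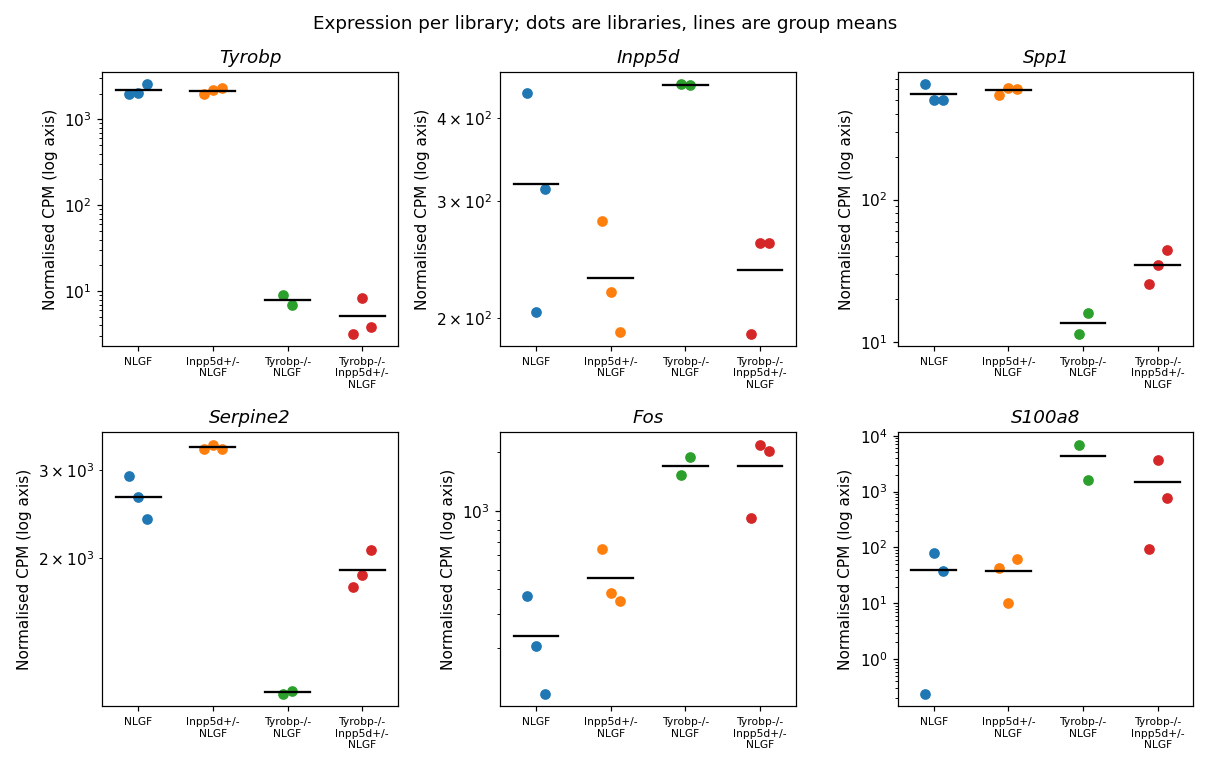
Normalised CPM on log axes for 6 genes, with each dot a library, each line a group mean and the 4 genotypes along the horizontal axis. Tyrobp fell from a mean of 2190 in NLGF to 7.98 in Tyrobp-/-;NLGF, and Spp1 had means of 549, 587, 13.7 and 34.7 from left to right.

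The comparison of Tyrobp-/-;NLGF with NLGF asked what the loss of the TREM2 adaptor does to microglia that face amyloid. The transcripts that define the disease-associated (DAM) state were lower. Of 25 fixed DAM stage 2 genes, those known to need TREM2, 18 fell and none rose, with a median log2 fold change of -2.51 (camera adjusted p = 2.58e-49, and adjusted p = 0.013 with an estimated correlation). Adjusted over the list alone, 24 were lower. Spp1, the secreted protein osteopontin, went from 549 ± 83.7 to 13.7 ± 3.11 CPM (log2 fold change -5.33, SE 0.29, adjusted p = 0.000122). Ank, a pyrophosphate transporter, fell from 942 ± 89.6 to 81.6 ± 2.03 CPM, and the chemokine gene Ccl6 from 2450 ± 151 to 746 ± 19.2. Cadm1, a cell adhesion gene, had a log2 fold change of -1.14 (SE 0.0855, adjusted p = 0.000379). In all, 176 of 20390 genes changed, 52 higher and 124 lower.

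Among the genes with the largest decreases were Mamdc2 (83.5 ± 13.2 to 0.0868 ± 0.0181 CPM), the lysyl oxidase gene Lox (28 ± 8.42 to 0.179 ± 0.253), Gpnmb (47.7 ± 4.02 to 0.736 ± 1.01) and Tmem163 (25.1 ± 5.39 to 1.13 ± 0.131). Of the 10 DAM stage 1 genes, 3 fell, namely Tyrobp itself and the cathepsin genes Ctsb and Ctsd. Adjusted over the list alone 6 were lower and 1 higher (camera adjusted p = 6.87e-07, and adjusted p = 0.11 with an estimated correlation). These counts and list tests include Tyrobp, whose fall is given by the genotype, and the list was not tested without it. Ctsb fell from 7920 ± 273 to 5040 ± 1.48 CPM.

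Genes of cholesterol synthesis were also lower. Of 21 members, 2 fell, Hmgcs1 (53.6 ± 3.82 to 26.1 ± 0.742 CPM) and the regulator Srebf2 (50.4 ± 9.73 to 22.5 ± 0.967), and adjusted over the list alone 12 were lower. The list median was -0.92 (camera adjusted p = 1.35e-12, and adjusted p = 0.018 with an estimated correlation). Of the 33 lysosomal genes 4 fell, Ctsb, Ctsd, Gusb and Ctsl (3610 ± 207 to 2020 ± 62.7 CPM), and Gusb and Ctsl are in the DAM stage 2 list as well. Of the 27 lipid handling genes 4 fell, Scd2, Soat1, the fatty acid binding protein gene Fabp5 and the lipase gene Lpl (335 ± 44 to 22.3 ± 4.18), of which Fabp5 and Lpl are in the DAM stage 2 list. Adjusted over each list alone, 12 lysosomal genes were lower and 2 higher, and 6 lipid handling genes were lower and 1 higher. Of the 21 glycolysis genes 2 fell, the glucose transporter gene Slc2a1 (170 ± 8.86 to 75.6 ± 13.2 CPM) and Pfkl, and 9 were lower adjusted over the list alone. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.099, 0.39 and 0.11), while with fry the lysosomal and glycolysis lists passed (adjusted p = 0.0066 and 0.025). The ribosomal protein and oxidative phosphorylation lists had lower medians of -0.23 and -0.09 with no member called, and an adjusted p of 0.44 and 0.69 with an estimated correlation.

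Of 29 homeostatic microglia genes none fell and 3 rose: Tmem119 (3580 ± 210 to 5600 ± 38.3 CPM), Cst3 (15600 ± 1760 to 25100 ± 2060) and Sparc (3010 ± 131 to 4080 ± 214). Adjusted over the list alone 8 were higher and 1 lower, and the list median was 0.08 (camera adjusted p = 0.00592, and adjusted p = 0.39 with an estimated correlation). Of 30 immediate early and dissociation response genes 6 rose, and 16 were higher and 1 lower adjusted over the list alone, with a median of 0.79 (camera adjusted p = 2.02e-15, and adjusted p = 0.11 with an estimated correlation). The feedback inhibitor gene Socs3 rose from 41.7 ± 5.77 to 218 ± 42.9 CPM, Junb from 280 ± 32.5 to 526 ± 64.4 and Fos had a log2 fold change of 2.88 (SE 0.49). Of the 27 TYROBP-coupled and paired receptor genes, Lilra6, Siglece and Pirb rose and Siglecf fell (130 ± 28.8 to 42.2 ± 2.33 CPM), with adjusted p = 0.11 for the list with an estimated correlation. Reads of these related receptor genes may be divided between family members. The list mean (log2 difference from NLGF) was 2.197 and 1.83 in the Tyrobp-/-;NLGF libraries and 0.533, 1.695 and 1.407 in compound replicates 1, 2 and 3. Compound replicate 1, with the lowest neutrophil mean of the Tyrobp-/- libraries, thus lay within the range of the other genotypes (-0.361 to 0.585). Whether neutrophil RNA contributed to the higher receptor transcripts was not tested. The lipoprotein receptor gene Scarb1 fell, and Abi3, an Alzheimer risk gene, rose (193 ± 10.9 to 289 ± 8.82 CPM), each in a list that did not pass.

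Markers of blood-derived myeloid cells differed between the Tyrobp genotypes beside these groups. S100a8, an abundant neutrophil transcript, was at 6920 and 1600 CPM in the Tyrobp-/-;NLGF libraries and at 94, 3650 and 783 in the compound mutant, against 0.24 to 80.9 in the 6 other libraries. Ngp, printed after its values were seen, and Camp had the same order of libraries within both Tyrobp-/- groups. No member of the neutrophil or monocyte list passed the threshold over all genes, and adjusted over each list alone 10 of 12 and 7 of 16 were higher (camera adjusted p = 7.56e-05 and 2.11e-06, and adjusted p = 0.41 and 0.11 with an estimated correlation). The genes with the largest increases included some with a wide spread over the same libraries, such as S100a11 (4.49 ± 1.25 to 86.2 ± 60.3 CPM), Plbd1 (2.4 ± 1.4 to 76.6 ± 40.1 CPM), the haptoglobin gene Hp (0.797 ± 0.914 to 121 ± 89.6) and Padi4, which had 0 counts in NLGF and was at least 174-fold higher against a floor of 3 counts per library. Of the 52 higher genes, 8 (15.4%) had the library order of S100a8 within both Tyrobp-/- groups, as did 9.72% of all genes. The inflammatory cytokine list had no member called (camera adjusted p = 0.00592, and adjusted p = 0.11 with an estimated correlation). The lists for interferon response, both MHC classes, complement, phagocytic receptors, TREM2 signalling, Alzheimer risk genes, proliferation, integrated stress, sex-linked genes, neurons, astrocytes, oligodendrocytes, endothelium, border-associated macrophages, lymphocytes and erythroid cells did not pass with the preset correlation.

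The count of 176 genes was 31 and 36 without Tyrobp-/-;NLGF replicate 1 and 2, and 88 and 108 without NLGF replicate 2 and 3. In the fits with 31 and 36 genes, the lone Tyrobp-/-;NLGF library was assumed to vary like the other groups. The count was 10 with a covariate for neutrophil markers and 27 without the 2 libraries with most S100a8, both chosen after seeing the data, and 1156 with DESeq2. With that covariate the 52 higher and 124 lower genes kept their sign. Their median log2 fold changes went from 1.33 to 1.24 and from -1.38 to -1.35, and their median SE from 0.196 to 0.351 and from 0.202 to 0.354. The DAM stage 2 median was -2.78, and Spp1 passed at -5.27 (SE 0.446, adjusted p = 0.00626). S100a11 went from 4.27 (SE 0.809) to 0.68 (SE 0.763) and Hp from 7.42 (SE 1.4) to 2.17 (SE 1.02). Plbd1 went from 4.99 (SE 0.733) to 2.04 (SE 0.627). Padi4, without counts in NLGF, kept more of its fold change and went from 12.2 (SE 2.07) to 9.05 (SE 2.89). None of these genes passed with the covariate.

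The same loss was examined on the Inpp5d+/- background, by comparing the compound mutant with Inpp5d+/-;NLGF. Here 54 genes rose and 129 fell. Of the 25 DAM stage 2 genes 19 fell, with a median of -2.10 (camera adjusted p = 6.37e-46, and adjusted p = 0.0078 with an estimated correlation), and 23 were lower adjusted over the list alone. Spp1 fell from 587 ± 34.8 to 34.7 ± 9.29 CPM and the cystatin gene Cst7 from 891 ± 154 to 113 ± 42.9. Of the 21 cholesterol synthesis genes 9 fell (adjusted p = 0.0078 with an estimated correlation), among them Insig1 (65.4 ± 10.5 to 24 ± 6.94 CPM) and Msmo1 (200 ± 14.7 to 101 ± 18), and 15 were lower adjusted over the list alone. The transcription factor gene Bhlhe40 fell from 81.6 ± 9.28 to 4.09 ± 1.39 CPM. Tmem119 and Sparc rose, as did Socs3 (55.9 ± 15.6 to 215 ± 19.8). This comparison shares no library with that of Tyrobp-/-;NLGF and NLGF. Of the genes called there, 22 higher and 76 lower genes were called here in the same direction, where 0.14 and 0.78 would be shared by independent lists. The lists are not fully independent, because both comparisons come from the same model with a shared estimate of spread. In both, the title numbers of the Tyrobp genotypes also fall in separate ranges. The shared genes therefore cannot separate the Tyrobp genotype from handling or litter. No neutrophil marker passed over all genes, and adjusted over the list alone 9 of 12 were higher (camera adjusted p = 0.0128, and adjusted p = 0.59 with an estimated correlation). Of the 16 monocyte markers none passed and 5 were higher over the list alone (camera adjusted p = 0.000353, and adjusted p = 0.24 with an estimated correlation). The total of 183 was 104, 79 and 90 without Inpp5d+/-;NLGF replicate 1, 2 and 3, and 66 and 79 without compound replicate 1 and 2. It was 39 with the neutrophil covariate, 50 without the 2 libraries with most S100a8 and 1195 with DESeq2.

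Against NLGF, the compound mutant had 49 higher and 129 lower genes. Of the DAM stage 2 genes 20 fell, with a median of -2.02 (camera adjusted p = 1.08e-46, and adjusted p = 0.011 with an estimated correlation). Gpnmb fell from 47.7 ± 4.02 to 0.05 ± 0.0265 CPM, Postn from 10.2 ± 3.43 to 0.361 ± 0.304 and Mamdc2 from 83.5 ± 13.2 to 4.59 ± 2.28. Of the cholesterol synthesis genes 4 fell, including Sqle (20 ± 2.94 to 3.49 ± 1.3 CPM), with adjusted p = 0.011 for the list with an estimated correlation. Of the immediate early genes 10 rose and 1 fell (adjusted p = 0.1 with an estimated correlation), with Egr1 going from 145 ± 64 to 565 ± 158 CPM. No neutrophil marker passed over all genes, and adjusted over the list alone 10 of 12 were higher (camera adjusted p = 0.00577, and adjusted p = 0.57 with an estimated correlation). Of the 16 monocyte markers none passed and 7 were higher over the list alone (camera adjusted p = 0.000513, and adjusted p = 0.27 with an estimated correlation). Hcst, which encodes the adaptor DAP10 and starts at position 30417712 next to Tyrobp, fell from 46.4 ± 2.37 to 7.71 ± 4.15 CPM. Lgi4 and Fxyd3, which overlap each other on chromosome 7 so that some of their reads cannot be told apart without strand, rose from 2.21 ± 0.608 to 19.6 ± 5.4 and from 1.26 ± 0.261 to 9.64 ± 2.96 CPM. The total of 178 became 62 and 100 without NLGF replicate 2 and 3, 109 without either Tyrobp-/-;NLGF library, and 80 and 75 without compound replicate 1 and 2. It was 27 with the neutrophil covariate, 64 without the 2 libraries with most S100a8 and 1147 with DESeq2.

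**Figure D2:**
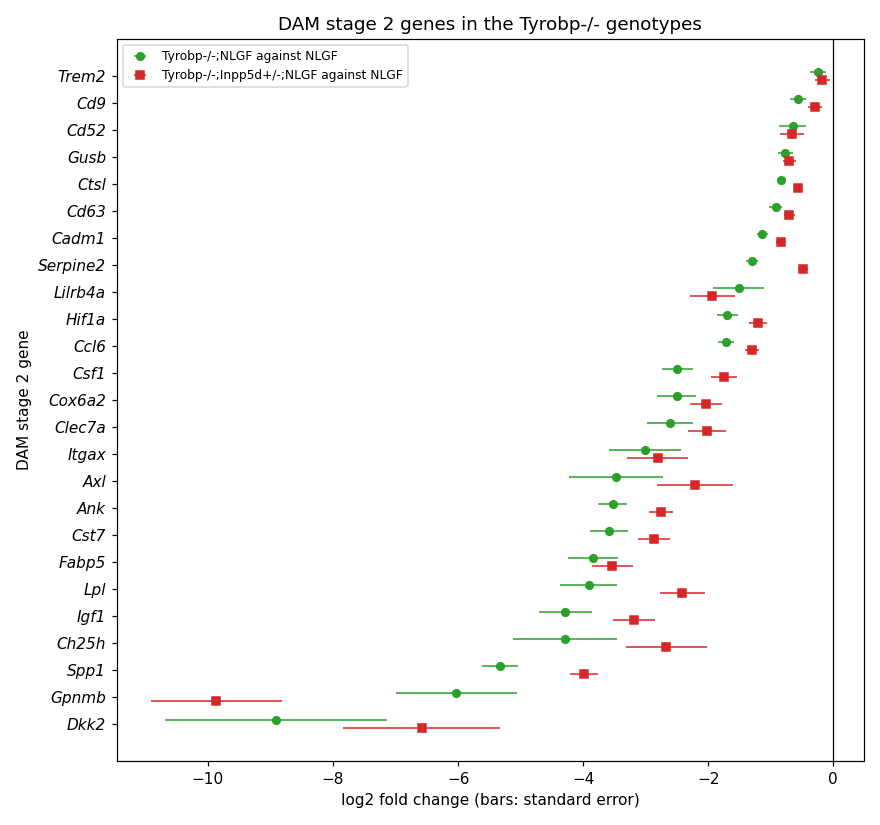
Log2 fold changes against NLGF of the 25 DAM stage 2 genes on the horizontal axis, with circles for Tyrobp-/-;NLGF, squares for the compound mutant and bars for the standard error. All values lie below 0, with medians of -2.51 and -2.02.

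The effect of Inpp5d+/- alone was examined by comparing Inpp5d+/-;NLGF with NLGF. No gene passed the edgeR threshold among 20390, where 951 genes had an unadjusted p below 0.05 and 1020 would by chance. DESeq2 called 38 genes and limma-voom 0. The DAM stage 2 and homeostatic lists did not pass either. Serpine2, a DAM stage 2 gene, was at 2650 ± 264 CPM in NLGF and 3330 ± 38.2 in Inpp5d+/-;NLGF, without passing (adjusted p = 0.952), and Ptpn22 was at 0.117 ± 0.129 and 5.74 ± 3.43 (adjusted p = 0.878). Among genes of at least 5 CPM the median SE was 0.24, and in simulated data 5.97% of 1.5-fold changes were called, so changes of that size were mostly not detectable in single genes. The immediate early list alone passed with the preset correlation, with a median of 0.27 (camera adjusted p = 1.31e-05, and adjusted p = 0.99 with an estimated correlation), and its call was absent without NLGF replicate 3.

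The comparison of the compound mutant with Tyrobp-/-;NLGF asked whether the Inpp5d+/- genotype alters the Tyrobp-/- profile. Mamdc2 and Fzd9, which encodes a Wnt receptor, were higher, and no other gene passed. Mamdc2 was at 0.0868 ± 0.0181 CPM in Tyrobp-/-;NLGF and 4.59 ± 2.28 in the compound mutant (adjusted p = 0.0441), against 83.5 ± 13.2 in NLGF. Fzd9 had 0 counts in Tyrobp-/-;NLGF and 1.93 ± 0.548 CPM in the compound mutant, at least 33.6-fold higher against a floor of 3 counts per library. With any library left out, both calls were lost, except that of Mamdc2 without compound replicate 1 (adjusted p = 0.000191), and 0 or 1 gene was called in each such fit. Neither gene passed in limma-voom or with 1 surrogate variable, and DESeq2 called 63 genes.

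DAM stage 2 genes lay higher in the compound mutant as a list, with a median log2 fold change of 0.47 and no member called over all genes. The list means per library (log2 difference from NLGF) overlapped, at -2.641 and -2.831 in Tyrobp-/-;NLGF and -2.681, -2.401 and -1.868 in compound replicates 1, 2 and 3. In direction 22 of 25 were higher. Adjusted over the list alone 11 were higher and 1 lower. The list test passed with the preset correlation (camera adjusted p = 2.83e-10) and not otherwise, with adjusted p = 0.34 with an estimated correlation and 0.3 with fry. Without compound replicate 3 the median was 0.267. Serpine2 was at 1080 ± 11.4 CPM in Tyrobp-/-;NLGF and 1890 ± 168 in the compound mutant (log2 fold change 0.81, SE 0.10, adjusted p = 0.0589). Spp1 was at 13.7 ± 3.11 and 34.7 ± 9.29 CPM (adjusted p = 0.566), and the sialyltransferase gene St8sia6 at 6.33 ± 0.94 and 25.9 ± 12 (adjusted p = 0.447). Tcirg1, a proton pump subunit gene, was at 73.6 ± 10.8 and 124 ± 2.05 CPM (adjusted p = 0.447). The lists for interferon response and MHC class I were higher and those for MHC class II, paired receptors, monocytes and neutrophils lower with the preset correlation, with an adjusted p of 0.94, 0.7, 0.94, 0.34, 0.7 and 0.7 with an estimated correlation. All 11 tested neuron markers were higher in direction, with a median of 4.88 and none called (camera adjusted p = 0.181), and compound replicate 1 alone had a high list mean.

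Of the 176 genes called in Tyrobp-/-;NLGF against NLGF, 88.1% had the opposite sign in the compound mutant against Tyrobp-/-;NLGF, 111 of 124 lower genes and 44 of 52 higher genes. Both comparisons use the same 2 Tyrobp-/-;NLGF libraries, and such a share lies above an even split with no effect. In 20 simulations with no effect of either gene the share was 94.2% on average (89.8 to 97.7) among as many top genes. With a Tyrobp effect and no Inpp5d effect it was 71.4% (67.9 to 75.2), over the 290 to 393 genes called in those simulations. The observed share lay outside both ranges, but this decides nothing on an effect of Inpp5d. The simulations drew each gene independently, so their ranges leave out shifts that many genes of a library share. The simulations with a Tyrobp effect also differed from the data in other ways. In them 229 to 284 genes were called in the same direction in both Tyrobp-/- groups against NLGF, where 112 were observed. Over all genes the covariance of fold changes was -1.78, against -1.46 with no effect and -1.33 with a Tyrobp effect alone, and the correlation was -0.54 against -0.61 and -0.45. With the Tyrobp effect from 1 Tyrobp-/-;NLGF library and the compound effect against the other, the share was 83.3% and 71%. Here the comparisons share no Tyrobp-/-;NLGF library. The simulated shares above therefore do not apply to these values, and no reference was simulated for them.

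The interaction asked whether the Inpp5d+/- effect differed between the Tyrobp genotypes. No gene passed in edgeR, where 958 had an unadjusted p below 0.05, and DESeq2 called 43 and limma-voom 0. Mamdc2 had the log2 difference 5.77 (SE 0.675, adjusted p = 0.0779). The DAM stage 2 list had a median of 0.47 and passed only with the preset correlation, with adjusted p = 0.93 with an estimated correlation. The immediate early list had a median of -0.43 and likewise passed only with the preset correlation (adjusted p = 0.93 with an estimated correlation).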

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

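The tests of this part were set out before their results were seen, except that the bootstrap spread used for single compound libraries was added after that median was known. The interaction test, of whether the Inpp5d+/- effect differed between the Tyrobp genotypes, passed for 2 lists with the preset correlation only. The DAM stage 2 list had a camera adjusted p of 2.22e-07 with the preset correlation and 0.93 with an estimated correlation. The immediate early list had 0.000262 and 0.93.

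DAM stage 2 genes lay higher in the compound mutant than in Tyrobp-/-;NLGF, a pattern noticed in these data and then tested on them. The list median was 0.549 (bootstrap SE over genes 0.149) with neutrophil markers in the model and 0.467 without. This cannot decide on neutrophil RNA in the Tyrobp-/-;NLGF libraries, because the covariate rests on few libraries within each group. In Tyrobp-/-;NLGF, the library with the higher neutrophil mean (8.358 against 6.316) also had the higher DAM stage 2 mean (-2.641 against -2.831). In the compound mutant, replicate 2 had the highest neutrophil mean (7.038) and replicate 3 the highest DAM stage 2 mean (-1.868). Neutrophil RNA therefore stays open. Chance spread of the libraries also stays open. Of the 10 arrangements of the 5 Tyrobp-/- libraries, 3, the real one included, gave a list mean difference at least as large in size as the real 0.419. Differences in either direction were counted, and the largest other was 0.584 in size. The list mean of compound replicate 1 (-2.681) lay below that of Tyrobp-/-;NLGF replicate 1 (-2.641). A single compound library also stays open as the source of much of the difference, since the median was 0.267 (bootstrap SE 0.0811) without compound replicate 3, 0.391 without replicate 2 and 0.627 without replicate 1. That loss of 1 Inpp5d copy may return part of these transcripts is a hypothesis. It cannot be told apart from chance spread or neutrophil RNA with these libraries.

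The counts of changed genes were set against other splits of the libraries. For Inpp5d+/-;NLGF against NLGF the real count was 0, so that each of the 10 splits had to give at least as many and the splits decide nothing there, and the highest other gave 2. For the compound mutant against NLGF, 1 of 10 splits, the real one, gave as many as 178 genes, and the highest other gave 0. Against Inpp5d+/-;NLGF, 1 of 10 splits, the real one, gave as many as 183, and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached. For the Tyrobp effect in an additive model over all 11 libraries, 1 of 100 splits drawn, the real one, gave as many as 1094 genes. The highest other gave 1, which argues against chance assignment of the Tyrobp labels for that count. Every other split put Tyrobp-/- and other libraries in the same arm, which by itself widens the spread. The splits cannot separate the Tyrobp genotype from anything that follows the same division of libraries, such as the separate title numbers.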

How the results depend on the processing

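The neutrophil covariate and the fit without the 2 libraries with most S100a8 were chosen only after the data were seen. Under RLE and upper-quartile scaling, the 6 counts of changed genes stayed within 1.5 times the values given, and the median log2 fold change of all genes moved by at most 0.018 in size. Of 139 called gene results, 28 passed under every alternative run and 0 changed sign. Of 51 uncalled gene results, 28 passed under some alternative and 5 changed sign under some. Where a count moved, the cause was not tested, except where fewer libraries, groups or a changed threshold give it by construction.

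For Tyrobp-/-;NLGF against NLGF (176 genes), DESeq2 called 1156 (531 higher and 625 lower), limma-voom 327, the fit on 2 groups only 75, a fold threshold of 1.5 left 40, the additive model called 1094, a threshold of 0.1 gave 380, the neutrophil covariate 10 and the fit without the 2 libraries with most S100a8 27. With each library left out the count ran from 31 to 201. For Inpp5d+/-;NLGF against NLGF (0 genes), DESeq2 called 38. For the compound mutant against Tyrobp-/-;NLGF (2 genes), no filter on low counts gave 1, DESeq2 63, limma-voom 0, 2 groups only 0, 1 surrogate variable 0, the neutrophil covariate 0 and the fit without the 2 libraries with most S100a8 0, and the count ran from 0 to 1 with each library left out. For the compound mutant against NLGF (178 genes), DESeq2 gave 1147 (545 higher and 602 lower), 2 groups only 28, the fold threshold 40, the threshold of 0.1 339, the covariate 27 and the fit without the 2 libraries 64, with a leave-one-out range of 62 to 152. Against Inpp5d+/-;NLGF (183 genes), these alternatives gave 1195 (590 higher and 605 lower), 61, 37, 376, 39 and 50, with a leave-one-out range of 66 to 183. For the interaction (0 genes), the stricter filter gave 2, DESeq2 43 and the threshold of 0.1 2, with a leave-one-out range of 0 to 1.

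The share with opposite sign (88.1%) ran from 78% to 96.8% with each library left out, and was 71% with the Tyrobp-/- effect from replicate 2 and the compound effect against replicate 1. Lists past the threshold with the preset correlation numbered 14, 1, 7, 16, 15 and 2 in the order of comparisons used above in this part. With an estimated correlation they numbered 2, 0, 0, 2, 2 and 0. With fry they numbered 10 for Tyrobp-/-;NLGF against NLGF, 0 for Inpp5d+/-;NLGF against NLGF, 0 for the compound mutant against Tyrobp-/-;NLGF, 8 against NLGF, 6 against Inpp5d+/-;NLGF and 0 for the interaction. Leave-one-out ranges were 13 to 16, 0 to 3, 4 to 10, 13 to 17, 14 to 18 and 1 to 7.

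The changes of sign were all in targeted genes or App, which passed in neither setting. The log2 fold change of App became -0.03478 (Tyrobp-/-;NLGF against NLGF) and -0.056 (Inpp5d+/-;NLGF against NLGF) in the additive model. For the compound mutant against NLGF it ran from -0.1435 to 0.01772 with each library left out. That of Tyrobp for Inpp5d+/-;NLGF against NLGF ran from -0.09467 to 0.1018. That of Inpp5d for the compound mutant against Inpp5d+/-;NLGF ran from -0.07398 to 0.2064, and was -0.05986 with 1 surrogate variable and -0.03139 without the 2 libraries with most S100a8. The sex covariate was not run, the additive model applies to the Tyrobp and Inpp5d effects only, and a fit on 2 groups does not apply to the interaction. No paired analysis was possible because the replicate numbers name samples in order and pair nothing. Depth limits genes near the floor of 0.0477 to 0.1 CPM.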

Other observations

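The tests of neutrophils in the gate, of dilution and of handling or litter in this part were chosen only after the results were seen. Interferon response genes lay higher in the compound mutant than in NLGF, with a list median of 0.54 and no member called (camera adjusted p = 1.71e-05, and adjusted p = 0.28 with an estimated correlation). In Tyrobp-/-;NLGF against NLGF the list did not pass (camera adjusted p = 0.164), and between both Tyrobp-/- groups it had adjusted p = 0.94 with an estimated correlation. The interferon-inducible gene Ifi47 rose from 2.03 ± 0.504 CPM in Inpp5d+/-;NLGF to 10.8 ± 4.41 in the compound mutant, and was at 16.4 ± 5.74 in Tyrobp-/-;NLGF. The chemokine gene Ccl12 rose in the compound mutant against NLGF, from 117 ± 11.5 to 263 ± 74.8 CPM. Among the 293 tested genes within 10 Mb of Tyrobp, 6 were called in the compound mutant against NLGF (2.05%, against 0.851% elsewhere, Fisher's exact p = 0.043). In Tyrobp-/-;NLGF against NLGF 3 were called (1.02% against 0.856%, Fisher's exact p = 0.74). This comparison was made after the data were seen. Fisher's test takes genes as independent, whereas Lgi4 and Fxyd3, which are in both counts, overlap each other. The p of 0.043 may therefore be too small.

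Neutrophil transcripts had higher means in the Tyrobp-/- libraries, with S100a8 at 94 to 6920 CPM against 0.24 to 80.9 in the others. Compound replicate 1 lay within the range of the others for Ltf (3.58 CPM), Ly6g (0.622), Retnlg (0.358), Mmp8 (0.245), Mmp9 (0.113) and Cxcr2 (0.0942), genes singled out after their values were seen. Its mean over the list, as a log2 difference from NLGF, was 2.015, against 2.481 in Inpp5d+/-;NLGF replicate 3. Of 10 tested neutrophil and mast cell markers other than S100a8 and S100a9, 9 (90%) had a higher mean in the Tyrobp-/- libraries, the exception being Csf3r, which microglia express as well, at 246 to 381 CPM in the 6 other libraries. That share restates the pattern and decides nothing, so neutrophils among the sorted cells stay open as its source. Dilution by other cells as the whole cause of the lower DAM stage 2 transcripts is argued against, since the homeostatic median was 0.083 (SD over members 0.348) and the DAM stage 2 median -2.51. Whether more neutrophils were in the tissue or in its blood was not tested.

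Immediate early transcripts were also higher as a list in the Tyrobp-/- groups with the preset correlation. Of 30 members 6 rose in Tyrobp-/-;NLGF against NLGF, 10 rose and 1 fell in the compound mutant against NLGF and 4 rose and 1 fell against Inpp5d+/-;NLGF, with adjusted p = 0.11, 0.1 and 0.24 for the list with an estimated correlation and 0.0097, 0.012 and 0.051 with fry. The list means per library were close, with 0.757 as the lowest of the Tyrobp-/- libraries and 0.72 as the highest of the others. The list median in Tyrobp-/-;NLGF against NLGF was 1.36 (bootstrap SE 0.189) with neutrophil markers in the model and 0.79 without. This cannot decide on neutrophils as the source, because both list means were related differently within the groups. In NLGF, replicate 1 had the lowest neutrophil mean (-2.598) and the highest immediate early mean (0.6). NLGF replicate 3 had the highest neutrophil mean (1.435) and the lowest immediate early mean (-0.607). In the compound mutant, replicate 1 had the lowest of both (2.015 and 0.757). Neutrophils as a source stay open. Handling or litter cannot be told apart from the Tyrobp genotype, because the numbers in the sample titles fall in separate ranges and 0 Tyrobp-/- libraries lie within the range of the others. A hypothesis is that part of the difference may come from how these mice were bred or processed, and an effect of Tyrobp loss stays open.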
